A study of Mus musculus with 12 samples.

How the data were processed

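RNA was measured in 12 libraries of mouse bone marrow-derived macrophages in 4 groups of 3: WT mock, WT with IL-4, KO mock and KO with IL-4. The groups and replicate numbers came from the sample titles. Per the labels, RNA was isolated with an RNeasy Micro kit. The library kit and its strandedness are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.7.2b, featureCounts of Subread 1.6.5 and edgeR, with genome build mm10.

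The deposited table gave whole-number read counts per gene and library, which the authors had not normalized, per the file headers. It also gave the authors' log2 CPM, the authors' log2 fold changes of 4 comparisons with adjusted p-values, and the gene length in bases that the authors' counting wrote, per the file headers. Which of edgeR's tests the authors used and which filter kept the 13715 genes are not given in the sources used here. The lowest total of a gene over the 12 libraries was 50 counts. Of the genes 11696 were protein coding and 1045 were long noncoding RNAs. Gene spans equalled those of GENCODE M21 for 13571 gene IDs. The handling of reads that match several places is not given, so values of near-identical genes such as Lyz1 and Lyz2 and the MHC genes are uncertain. The mitochondrial genes mt-Co2, mt-Atp6, mt-Atp8 and mt-Nd4l were not analysed here. Of the table's genes 14 were mitochondrial, and 16 entries shared a symbol with another, each of which counted on its own in a list.

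Library totals ran from 30651627 to 39136822 counts. Mitochondrial genes took 0.129% to 0.199% of the counts of a library and the 10 most abundant genes 18.0% to 27.0%. Replicates differed by more than sampling noise, since their chi-square per degree of freedom over genes whose counts summed to at least 20 ran from 10.6 to 84.6. In counts of the 13715 genes simulated from these libraries with 50 genes changed at each size, the test for KO against WT in mock found 16% of genes changed 1.25-fold, 60% at 1.5-fold and 100% at 2-fold, with 7 false calls. For the interaction it found 2%, 28% and 90%, with 5 false calls. In counts simulated with a length trend and no other change, the KO against WT test in mock called 554 genes without and 1 with the length and GC correction.

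The counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test, TMM factors (0.942 to 1.02) and filterByExpr, which removed 0 genes. One fit held a coefficient for each of the 4 groups, had 8 residual degrees of freedom and a common dispersion of 0.0115, and gave all contrasts: KO against WT in mock and with IL-4, IL-4 against mock in WT and in KO, and the interaction, which is the log2 fold change of IL-4 in KO minus that in WT. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast were called, and p-values without another name are from this test or, for lists, from camera. CPM values used TMM library sizes, and log2 CPM for the principal components used a prior count of 2. All tests were two-sided.

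Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 45 lists tested in each contrast, and again with the correlation estimated from the data. Lists, tests, contrasts, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named Stk11 and Lyz2. For each contrast of 2 groups it took up to 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the groups. For the interaction it took the 6 largest in each direction with the same adjusted p and mean. Chance alone separates groups of 3 in 10% of cases. Gene models with Gm, Rik, accession-like or clone-like names, ribosomal protein genes and histone genes were skipped. The rule further took up to 4 members with the smallest adjusted p per list and contrast, Arg1, Chil3, Retnla and Mrc1 in every contrast, and cell-type markers with their CPM. Any other gene is said to have been chosen after its values were seen.

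Whether equal replicate numbers mark related samples was checked by correlating, over 8126 genes with a mean log2 CPM over 3, the deviations of libraries from their group means. Mock and IL-4 libraries of the same number and genotype correlated at 0.229, 0.491 and 0.406 in WT and at 0.551, 0.579 and 0.518 in KO, and 11 of 12 libraries were closest to their own number. The numbers were therefore taken to pair mock with IL-4 libraries within a genotype, which rests on these correlations and on titles that number the samples within each genotype. The reported fit, fixed beforehand, did not use this pairing and treated the 12 libraries as independent. Its p-values for IL-4 and for the interaction therefore leave the pairing out. Results with the replicate block, which uses it, are given as an alternative.

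The alternatives were median-of-ratios factors, library size alone, no filter, CPM of at least 1 in 3 libraries, the replicate number as a block, only the groups compared, a log2 fold change of at least 1, limma-voom, DESeq2 1.42.0 and leaving out each library. Added after seeing the data were a correction for transcript length and GC content, with and without the block, and leaving out both KO 2 libraries, with and without that correction. The correction fitted splines with 5 degrees of freedom per library to genes with a mean log2 CPM over 2 and entered as offsets. GC content was known for 13692 genes, and the 23 without it were corrected with the median GC content in its place.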

Results

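Gene expression was measured by RNA-seq in macrophages grown from mouse bone marrow for 7 days with 40 ng/ml M-CSF, the growth factor that drives macrophage formation. The cells came from wild-type mice (WT) and from mice in which Cre recombinase, expressed from the lysozyme M locus (Lyz2), acts on a floxed Stk11 gene in myeloid cells (KO). Stk11 encodes LKB1, a kinase that activates AMPK and related kinases. Cultures were left unstimulated (mock) or received 20 ng/ml IL-4, the cytokine that drives alternative macrophage activation, for 24 h. The series title names mitochondrial metabolism and macrophage polarization as the subjects, so the comparisons were KO against WT under each condition, IL-4 against mock within each genotype, and the difference between the genotypes in the IL-4 response. Each of the 4 groups held 3 libraries, numbered 1 to 3 in the labels, with 30651627 to 39136822 counts per library over 13715 genes. The labels do not say that same-group samples came from separate animals, so the p-values measure the spread between these samples, which may in part be technical. In a principal component analysis, the first component (45.3% of the variance) separated IL-4 from mock libraries and the second (23.3%) separated WT from KO libraries.

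**Figure D1:**
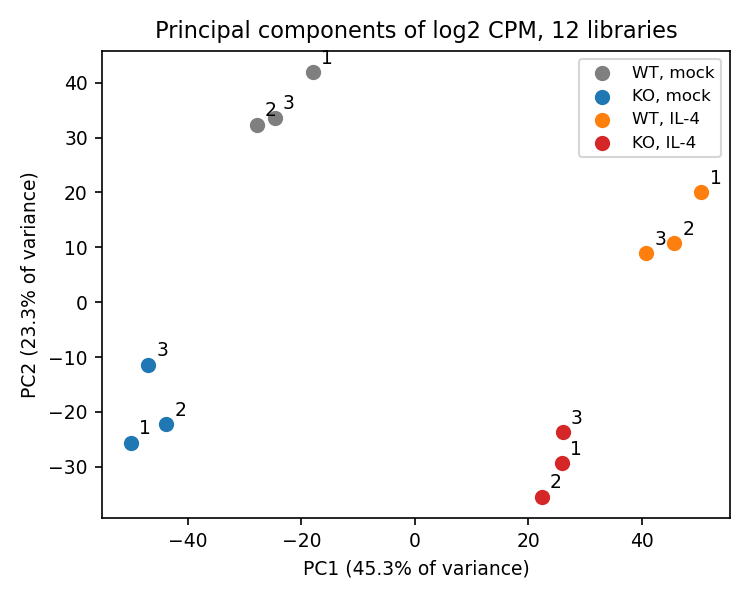
Position of each of the 12 libraries on the first (x axis, 45.3% of the variance) and second (y axis, 23.3%) principal component of log2 CPM (counts scaled to a common library size), coloured by group and marked with the replicate number. IL-4 libraries lie to the right of mock libraries, and WT libraries lie above KO libraries.

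Stk11 (ENSMUSG00000003068.16, chromosome 10, 80115803 to 80130682, plus strand, mm10) was lower in every KO library than in every WT library. In mock cultures it stood at 42.9 ± 4.52 CPM (counts scaled to a common library size; mean ± SD, n = 3 in each group throughout) in WT and 6.0 ± 2.5 in KO, a log2 fold change of -2.84 (SE 0.24, edgeR adjusted p = 3.8e-06). With IL-4 it stood at 45.2 ± 8.19 CPM in WT and 7.70 ± 1.92 in KO, a log2 fold change of -2.55 (SE 0.24, adjusted p = 9.0e-06). The counts cover the whole gene and do not separate the floxed exons from the others. Lyz2 (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321, minus strand), the lysozyme gene that carries the Cre insertion, divided the KO libraries. WT mock libraries held 39650 to 44640 CPM of Lyz2, KO mock libraries 1 and 3 held 21620 and 21040 CPM, and KO mock library 2 held 43.2 CPM. With IL-4 the WT libraries held 28470 to 31110 CPM, KO libraries 1 and 3 held 15360 and 15820 CPM, and KO library 2 held 43.4 CPM. Lyz2 was thus lower in every KO library than in every WT library of the same treatment. KO and WT therefore differed in Lyz2 as well as in Stk11. No comparison here separates Stk11 loss from the Cre insertion. Over all 3 KO libraries the Lyz2 log2 fold change was -1.57 (SE 1.40, adjusted p = 0.41) in mock and -1.51 (SE 1.40, adjusted p = 0.52) with IL-4. Without both KO 2 libraries, a setting chosen after seeing the data, it was -0.96 (adjusted p = 2.7e-05; 8.9e-06 to 0.54 over the alternative settings) and -0.92 (adjusted p = 2.3e-05; 2.3e-05 to 0.69).

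**Figure D2:**
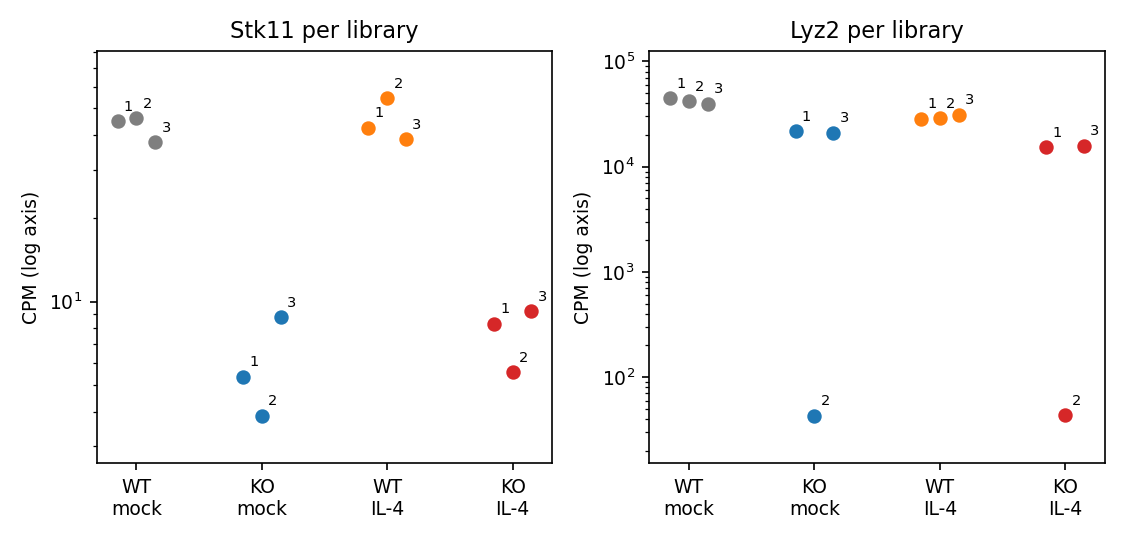
CPM (log axis) of Stk11 (left) and Lyz2 (right) in each library, by group, with the replicate number beside each point. All KO libraries lie below all WT libraries for Stk11, and KO library 2 stands apart for Lyz2 at 43.2 CPM in mock and 43.4 CPM with IL-4.

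In unstimulated KO macrophages, cell-cycle genes were lower than in WT, and more genes rose than fell in the antioxidant, hypoxia, cyclic AMP response and lysosome lists and in the nuclear-encoded OXPHOS, mitochondrial ribosome and TCA cycle lists. None of these lists passed with an estimated correlation (adjusted p = 0.11 to 0.68). Of 29 measured genes of G2 phase and mitosis 28 fell and none rose (camera adjusted p = 1.5e-21; adjusted p = 0.20 with an estimated correlation), among them Cdc20 (log2 fold change -1.61, SE 0.19) and Birc5 (-1.99, SE 0.24). Of 33 S-phase genes 22 fell and none rose (adjusted p = 8.6e-10; adjusted p = 0.29 with an estimated correlation). Uhrf1 changed by -2.10 (SE 0.20) and Tk1 by -1.71 (SE 0.19). The proliferation marker Mki67 changed by -2.32 (SE 0.31), and Ccnd1, which encodes cyclin D1, fell from 25.0 ± 8.08 to 4.59 ± 3.08 CPM. Of 25 NRF2-dependent antioxidant genes 19 rose and none fell (adjusted p = 3.4e-13; adjusted p = 0.11 with an estimated correlation), including heme oxygenase Hmox1 (1.03, SE 0.09), Gclm (0.78, SE 0.08) and Gsr (0.76, SE 0.08).

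Among the largest rises in mock KO cells were Thbs1, which encodes the secreted protein thrombospondin 1 (99.7 ± 19.0 CPM in WT, 1020 ± 269 in KO), the lipid-droplet gene Hilpda (21.9 ± 2.15 and 142 ± 7.44), the nuclear receptor gene Nr4a1 (10.6 ± 0.43 and 41.1 ± 2.34) and the chemokine gene Pf4 (47.0 ± 9.43 and 599.8 ± 37.8). Cx3cr1, the fractalkine receptor gene, fell from 143 ± 20.5 to 24.9 ± 6.75 CPM, and the potassium channel gene Kcnj2 fell from 40.5 ± 5.52 to 7.03 ± 1.66. Of 23 targets of CREB and its coactivators, which are kept inactive by kinases of the LKB1 pathway, 11 rose and 4 fell (adjusted p = 2.3e-06; adjusted p = 0.11 with an estimated correlation). Crem changed by 1.21 (SE 0.12) and Dusp1 by 1.08 (SE 0.10). Of 25 hypoxia genes 14 rose and 6 fell (adjusted p = 1.3e-05; adjusted p = 0.11 with an estimated correlation). Vegfa rose by 1.57 (SE 0.14) and Ndrg1 changed by -1.09 (SE 0.11). Of 53 lysosome genes 29 rose and 8 fell (adjusted p = 0.00015; adjusted p = 0.40 with an estimated correlation), including a rise of the protease gene Ctsl (1.39, SE 0.13) and falls of Mitf (-1.26, SE 0.15) and Atp6v0a1 (-0.90, SE 0.09).

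Nuclear genes of mitochondrial energy production were higher in mock KO cells by small amounts. Of 76 nuclear genes of oxidative phosphorylation (OXPHOS) 38 rose and none fell (adjusted p = 8.5e-10; adjusted p = 0.68 with an estimated correlation), among them Cyc1 (0.43, SE 0.06) and Ndufa12 (0.52, SE 0.10). Of 73 mitochondrial ribosome genes 41 rose and none fell (adjusted p = 1.2e-08; adjusted p = 0.68 with an estimated correlation). Of 32 genes of the TCA cycle list 12 rose (adjusted p = 0.0019; adjusted p = 0.35 with an estimated correlation). The member that fell, named after its value was seen, was Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase (-0.38, SE 0.12). The KO against WT fold changes in mock correlated with transcript length (Spearman's rho = -0.49 across genes, which are not independent replicates). Libraries of the same group also differed by length. Deviations from the group mean had rho = -0.51 in KO mock library 1, 0.49 in library 2 and 0.25 in library 3. The trend therefore did not follow genotype alone, and its cause was not tested. With a length and GC correction chosen after seeing the data 25 OXPHOS and 23 mitochondrial ribosome genes rose. Of 9 measured genes of mitochondrial DNA 5 fell, with mt-Nd5 at -0.86 (SE 0.17) and mt-Cytb at -0.54 (SE 0.15; adjusted p of the list = 0.057). Without WT mock library 1 or KO mock library 1 mt-Cytb was not called (adjusted p = 0.068 and 0.055; 0.00060 to 0.068 over the alternative settings). Of 15 fatty acid synthesis genes 8 fell and 2 rose (adjusted p = 0.020; adjusted p = 0.68 with an estimated correlation). Fasn changed by -1.27 (SE 0.19) and Fads2 by -1.45 (SE 0.22). Of 33 fatty acid oxidation genes 15 rose and 4 fell (adjusted p = 0.0497; adjusted p = 0.68 with an estimated correlation). Slc25a20 changed by 0.53 (SE 0.08) and Lpl by -0.78 (SE 0.11). That list was not called without WT mock library 1 or KO mock library 3 (adjusted p = 0.069 and 0.075; 0.011 to 0.076 over the alternative settings) or when scaled by library size alone.

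Immune genes of mock KO cells moved both ways. Of 12 MHC class II genes 6 fell and 1 rose (adjusted p = 0.15), with the transactivator gene Ciita at -1.48 (SE 0.23). Of 31 genes of classical inflammatory activation 13 rose and 7 fell (adjusted p = 0.014; adjusted p = 0.11 with an estimated correlation), with the lipopolysaccharide co-receptor gene Cd14 up (1.26, SE 0.14), Cd86 up (0.81, SE 0.12) and Tnf down (-0.85, SE 0.12). That list was not called with the length and GC correction. Of 20 immediate-early and stress genes 7 rose and 1 fell (adjusted p = 0.0016; adjusted p = 0.12 with an estimated correlation). Ier3 changed by 1.89 (SE 0.13) and Fos by 0.68 (SE 0.08). Markers of neutrophils were also higher, with 12 of 15 up and Csf3r down (-0.48, SE 0.10; adjusted p of the list = 0.00015; adjusted p = 0.68 with an estimated correlation). The neutrophil gene Ltf stood at 137, 329 and 191 CPM in KO mock libraries 1, 2 and 3 and at 33.0 to 90.2 CPM in the WT mock libraries. Of 4 erythroid and megakaryocyte markers Pf4 (3.67, SE 0.16), Klf1 (1.25, SE 0.43, adjusted p = 0.035) and Ppbp rose (adjusted p of the list = 3.7e-07; adjusted p = 0.11 with an estimated correlation). Klf1 was not called without both KO 2 libraries, nor without WT mock library 1 or 2 or any 1 of the KO mock libraries (adjusted p = 0.061 to 0.095), and its adjusted p lay between 0.017 and 0.11 over the alternative settings. Ppbp had 2 counts in the 3 WT libraries and 80 in the 3 KO libraries, a ratio of 38.6 (95% exact interval for counting error alone 10.3 to 324). The alternative activation gene Arg1 rose from 0.284 ± 0.070 to 1.5 ± 0.63 CPM (2.39, SE 0.32, adjusted p = 0.00011) and Chil3 rose by 1.66 (SE 0.25, adjusted p = 0.00024), while Mrc1 had 0.27 (SE 0.17, adjusted p = 0.23) and Retnla, with 10 counts in WT and 4 in KO, -1.25 (SE 1.10, adjusted p = 0.41).

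In total 4731 of 13715 genes differed between KO and WT in mock at an adjusted p under 0.05, 2147 higher and 2584 lower, of which 248 and 593 differed at least 2-fold. Scaled by library size alone, 1572 were higher and 2959 lower, whereas with the length and GC correction 2409 were higher and 2253 lower, with 3428 calls shared. More genes were also higher than lower without WT mock library 2 (2376 and 2263) and without WT IL-4 library 1 (2344 and 2336). Of 45 lists tested with camera 15 passed at the preset correlation and 0 with an estimated correlation. When adjusted over the list alone, 29 genes of G2 phase and mitosis and 23 of S phase fell, 45 OXPHOS and 44 mitochondrial ribosome genes rose, 12 CREB targets rose and 6 fell, and 32 lysosome genes rose and 8 fell. On the same basis 15 TCA cycle genes rose and 1 fell, 14 classical inflammatory genes rose and 7 fell, 7 immediate-early genes rose and 2 fell, 2 fatty acid synthesis genes rose and 9 fell, 16 fatty acid oxidation genes rose and 5 fell, and 2 MHC class II genes rose and 6 fell. The counts of the NRF2, hypoxia, neutrophil, erythroid and mitochondrial DNA lists did not move.

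With IL-4, the cell-cycle genes were again lower in KO than in WT, targets of CREB were again higher, hypoxia genes moved both ways, and genes of MHC class II were lower. Of these lists the CREB targets alone passed with an estimated correlation (adjusted p = 0.049). Of 29 genes of G2 phase and mitosis 28 fell and none rose (adjusted p = 2.1e-15; adjusted p = 0.30 with an estimated correlation). Ccnb2 changed by -1.51 (SE 0.25). Of 33 S-phase genes 23 fell and none rose (adjusted p = 6.8e-14; adjusted p = 0.28 with an estimated correlation). Mcm5 changed by -1.12 (SE 0.14). Of 23 CREB targets 11 rose and none fell (adjusted p = 7.35e-12). Thbs1 rose from 16.3 ± 4.22 to 465 ± 112 CPM (4.83, SE 0.26), Nr4a1 from 2.65 ± 0.47 to 19.9 ± 3.54 (2.91, SE 0.14) and Pde4b by 1.16 (SE 0.10). Of 25 hypoxia genes 10 rose and 4 fell, with a median of 0.08 (adjusted p = 5.6e-08; adjusted p = 0.073 with an estimated correlation). Hilpda changed by 2.90 (SE 0.11), Vegfa by 2.59 (SE 0.15) and Hif1a by 1.06 (SE 0.12). Of 12 MHC class II genes 7 fell and none rose (adjusted p = 2.6e-05; adjusted p = 0.28 with an estimated correlation), among them the class II transactivator gene Ciita (41.9 ± 7.65 CPM in WT, 16.7 ± 3.6 in KO; -1.32, SE 0.15) and H2-Eb1 (-1.05, SE 0.20).

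In the antioxidant, lysosome and autophagy lists more genes were higher than lower in KO cells with IL-4. Of 25 NRF2-dependent genes 12 rose and 1 fell (adjusted p = 8.6e-06; adjusted p = 0.30 with an estimated correlation). Hmox1 changed by 1.01 (SE 0.09). Of 53 lysosome genes 22 rose and 5 fell (adjusted p = 0.00014; adjusted p = 0.38 with an estimated correlation). Ctsl changed by 1.49 (SE 0.13). Of 31 autophagy genes 9 rose and Atg9b (-1.25, SE 0.18) fell (adjusted p = 0.0023; adjusted p = 0.38 with an estimated correlation). Of 15 fatty acid synthesis genes 7 fell and 1 rose (adjusted p = 0.0032; adjusted p = 0.50 with an estimated correlation). Elovl6 changed by -1.33 (SE 0.20) and Scd2 by -0.90 (SE 0.15). Of 76 OXPHOS genes 10 fell and none rose (adjusted p = 0.0011; adjusted p = 0.78 with an estimated correlation). Sdhc changed by -0.30 (SE 0.07), and 31 genes of the list fell with the length and GC correction and 2 without both KO 2 libraries. The list was not called without WT IL-4 library 2 (adjusted p = 0.22; 2.2e-06 to 0.22 over the alternative settings). Neutrophil markers were higher for 9 of 15 and lower for none (adjusted p = 6.1e-05; adjusted p = 0.50 with an estimated correlation). The neutrophil gene Ltf stood at 62.2, 227 and 137 CPM in KO libraries 1, 2 and 3 and 16.4 to 47.9 CPM in the WT libraries. Of the 4 erythroid and megakaryocyte markers Pf4 (3.47, SE 0.16), Ppbp (2.98, SE 0.63) and Klf1 (1.6, SE 0.51, adjusted p = 0.042) rose (adjusted p of the list = 1.3e-07; adjusted p = 0.049 with an estimated correlation). Klf1 was again not called without both KO 2 libraries, nor without any 1 of the KO mock libraries, WT IL-4 library 1 or 3 or KO IL-4 library 1 or 2 (adjusted p = 0.051 to 0.15; 0.024 to 0.15 over the alternative settings).

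The markers of alternative activation did not move together between the genotypes under IL-4. Arg1, which encodes arginase 1, was higher in KO (126 ± 6.43 CPM in WT, 289 ± 23.1 in KO; 1.20, SE 0.12, adjusted p = 1.5e-05), and Retnla, which encodes a secreted resistin-like protein, was lower (214 ± 39.8 and 89.2 ± 20.1; -1.26, SE 0.15, adjusted p = 6.2e-05). Chil3 had 0.54 (SE 0.24, adjusted p = 0.13) and the mannose receptor gene Mrc1 had 0.13 (SE 0.16, adjusted p = 0.62). Of 43 genes of the IL-4 activation list 10 were higher and 14 lower in KO (adjusted p = 0.67), including Il1rn (1.84, SE 0.12) and Flt1 (-1.69, SE 0.17). Under IL-4, 2579 genes differed between KO and WT, 1176 higher and 1403 lower, of which 227 and 320 differed at least 2-fold. The count was 1596 without both KO 2 libraries and 1658 without WT IL-4 library 1, and without KO IL-4 library 1 954 were higher and 928 lower. When adjusted over the list alone, 28 S-phase genes fell, 11 CREB targets rose and 1 fell, 14 NRF2-dependent genes rose and 1 fell, 1 MHC class II gene rose and 9 fell, and 10 neutrophil markers rose and 1 fell. On the same basis 5 OXPHOS genes fell, 13 autophagy genes rose and 1 fell, 1 fatty acid synthesis gene rose and 8 fell, and 12 genes of the IL-4 list were higher and 17 lower. The counts of the G2 and mitosis, hypoxia, lysosome and erythroid lists did not move. Of the genes higher in KO 750 were shared between mock and IL-4 (184.1 for independent lists), and 998 of the lower ones (264.3), while 19 were called in opposite directions. Mock and IL-4 libraries with the same number correlated within a genotype, so part of the excess may come from shared cultures.

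In WT macrophages IL-4 raised the known genes of alternative activation and of MHC class II. Retnla rose from 0.101 ± 0.024 to 214 ± 39.8 CPM (log2 fold change 11.01, SE 0.30), Arg1 from 0.284 ± 0.070 to 126 ± 6.43 CPM (8.79, SE 0.21), Chil3 from 30.3 ± 9.82 to 4762 ± 474 CPM (7.29, SE 0.31) and Mrc1 from 36.3 ± 3.88 to 337 ± 68.3 CPM (3.21, SE 0.17). Of 43 genes of the IL-4 activation list 37 rose and 3 fell (adjusted p = 6.8e-105, and 3.8e-06 with an estimated correlation), including the cytokine-signalling inhibitor Cish (8.14, SE 0.20) and the PD-1 ligand gene Pdcd1lg2 (7.35, SE 0.21). Of 12 MHC class II genes 8 rose and none fell (adjusted p = 8.3e-17, and 0.027 with an estimated correlation). Ciita changed by 3.78 (SE 0.18) and H2-Eb1 by 3.19 (SE 0.22). Cx3cr1 fell from 143 ± 20.5 to 6.20 ± 1.40 CPM (-4.53, SE 0.25), and the iron exporter gene Slc40a1 changed by -2.64 (SE 0.12).

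In WT cells more genes also rose than fell with IL-4 in the nuclear OXPHOS, TCA cycle, cholesterol synthesis and unfolded protein response lists, none of which passed with an estimated correlation (adjusted p = 0.27 to 0.69). The lists of glycolysis (14 of 28 rose and 7 fell; adjusted p = 0.060), fatty acid oxidation (0.15), fatty acid synthesis (0.315), the pentose phosphate pathway (0.315) and glutamine metabolism (0.85) were not called. Of 76 nuclear OXPHOS genes 62 rose and none fell (adjusted p = 1.1e-14; adjusted p = 0.60 with an estimated correlation). Atp5b changed by 0.64 (SE 0.06), Cyc1 by 0.68 (SE 0.06) and Cox8a by 0.83 (SE 0.09). Of 32 TCA cycle genes 17 rose, with Idh3a at 0.68 (SE 0.06), and Suclg2 fell (-0.74, SE 0.08; adjusted p of the list = 0.0013; adjusted p = 0.40 with an estimated correlation). Of 24 genes of the unfolded protein response 15 rose and 1 fell (adjusted p = 1.6e-06; adjusted p = 0.27 with an estimated correlation). Pdia4 changed by 1.69 (SE 0.07). Of 24 cholesterol synthesis genes 13 rose and none fell (adjusted p = 0.0010; adjusted p = 0.69 with an estimated correlation). Dhcr7 changed by 1.22 (SE 0.07). Of 17 MHC class I genes 9 rose and none fell (adjusted p = 0.00039; adjusted p = 0.60 with an estimated correlation). Of 37 interferon-stimulated genes 16 rose and 2 fell (adjusted p = 0.0016; adjusted p = 0.60 with an estimated correlation). Gbp2 changed by 1.99 (SE 0.13). Of 15 genes of osteoclast formation and cell fusion 7 rose and 2 fell (adjusted p = 0.00073; adjusted p = 0.50 with an estimated correlation). Ocstamp changed by 7.28 (SE 0.32). In total 3658 genes differed, 1871 higher and 1787 lower, of which 520 and 381 differed at least 2-fold. With the length and GC correction and the replicate block 2414 were higher and 2543 lower. When adjusted over the list alone, 38 genes of the IL-4 list rose and 3 fell, 10 MHC class II, 67 OXPHOS and 10 MHC class I genes rose, 17 interferon-stimulated genes rose and 2 fell, and 7 genes of osteoclast formation rose and 3 fell. The counts of the TCA cycle, unfolded protein response and cholesterol lists did not move.

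In KO macrophages IL-4 raised the same lead markers. Retnla rose from 4 counts in the 3 mock libraries to 89.2 ± 20.1 CPM, Arg1 from 1.5 ± 0.63 to 289 ± 23.1 CPM (7.61, SE 0.17), Chil3 from 96.3 ± 36.9 to 6903 ± 1063 CPM (6.16, SE 0.29) and Mrc1 from 43.6 ± 9.16 to 369.5 ± 48.9 CPM (3.08, SE 0.17). Of 43 genes of the IL-4 activation list 36 rose and 2 fell (adjusted p = 4.3e-100, and 6.7e-06 with an estimated correlation). Of 12 MHC class II genes 9 rose and 1 fell (adjusted p = 1.7e-11; adjusted p = 0.089 with an estimated correlation). Ciita changed by 3.93 (SE 0.21). Of 17 MHC class I genes 11 rose (adjusted p = 0.00014; adjusted p = 0.76 with an estimated correlation), of 24 unfolded protein response genes 13 rose (adjusted p = 0.00037; adjusted p = 0.76 with an estimated correlation), and none of either list fell. Without both KO 2 libraries 7 unfolded protein response genes rose. Of 25 NRF2-dependent genes 13 fell and 2 rose (adjusted p = 0.00064; adjusted p = 0.76 with an estimated correlation). Gsta3 changed by -1.74 (SE 0.15) and Prdx1 by -0.77 (SE 0.09). Of 76 nuclear OXPHOS genes 5 rose and none fell (adjusted p = 0.98), with Atp5b at 0.33 (SE 0.06), while 9 rose and 8 fell with the replicate block, 31 rose and 5 fell with the length and GC correction and the block, and 1 rose without both KO 2 libraries. Of 73 mitochondrial ribosome genes 13 fell and none rose (adjusted p = 0.014; adjusted p = 0.91 with an estimated correlation). Mrpl33 changed by -0.51 (SE 0.10). In that list 24 fell and 1 rose with the replicate block, 6 fell without both KO 2 libraries, and the list was not called with the length and GC correction and the block, nor without KO mock library 1 (adjusted p = 0.13; 0.0022 to 0.21 over the alternative settings). The IL-4 fold changes of KO cells correlated with transcript length across genes (rho = 0.34). In total 4152 genes differed, 2198 higher and 1954 lower, of which 661 and 307 differed at least 2-fold. When adjusted over the list alone, 38 genes of the IL-4 list rose and 2 fell, 13 MHC class I and 15 unfolded protein response genes rose, 2 NRF2-dependent genes rose and 14 fell, 1 OXPHOS gene rose and 7 mitochondrial ribosome genes fell, while the MHC class II count did not move. Scaled by library size alone, 2513 were higher and 1493 lower, whereas with the length and GC correction and the replicate block 2669 were higher and 3050 lower.

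The IL-4 responses of the genotypes correlated across genes. Over all 13715 genes, log2 fold changes in KO and WT had Pearson's r = 0.828 and Spearman's rho = 0.607; these are across genes, which are not independent replicates. Over the 5551 genes that passed the test in at least one genotype, a selection on the fold changes themselves that by itself raises a correlation, the values were r = 0.895 and rho = 0.818, with a total least squares slope of 0.967. Both genotypes shared 1184 of the higher genes (299.9 for independent lists) and 1058 of the lower ones (254.6), and 17 genes were called in opposite directions.

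**Figure D3:**
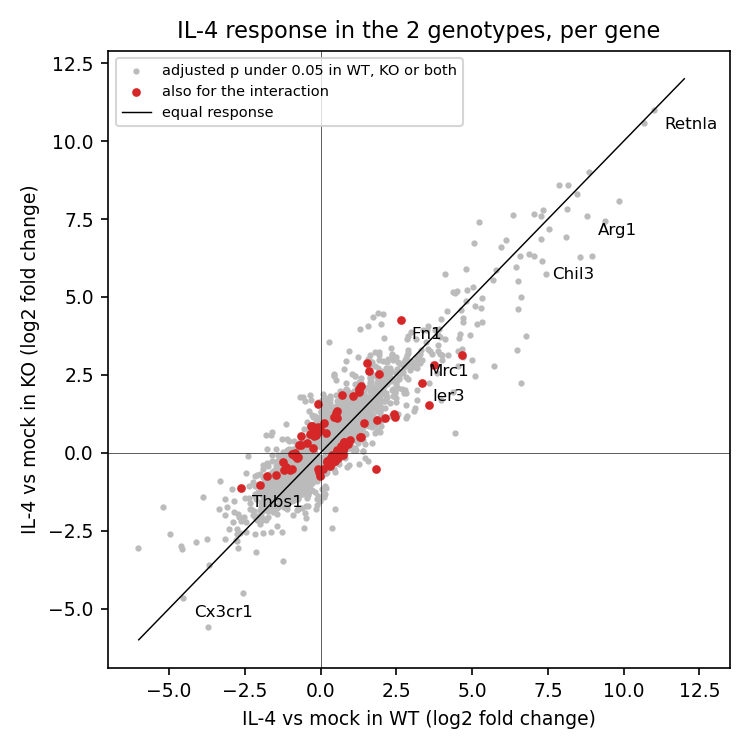
Log2 fold change of IL-4 against mock in WT (x axis) and in KO (y axis) for the 5551 genes with an adjusted p under 0.05 in WT, KO or both, with genes that also passed the test of the difference in red. Most points lie near the line of equal response (r = 0.895), and Fn1, Thbs1 and Ier3 lie off it.

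The test of the difference between the genotypes in the IL-4 response compared KO with WT cells, which differed in both Stk11 and Lyz2. Nuclear OXPHOS genes responded less to IL-4 in KO than in WT. The interaction log2 fold change was below 0 for 76 of 76 genes, with a median of -0.42 (adjusted p = 5.0e-38; adjusted p = 0.56 with an estimated correlation). Of these genes 7 passed the test over all genes, 58 when adjusted over the list alone and 60 with the replicate block, among them Cyc1 (-0.59, SE 0.09, adjusted p = 0.015), Uqcr10 (-0.59, SE 0.11, adjusted p = 0.033) and Atp5o (-0.60, SE 0.12, adjusted p = 0.040). Cyc1 went from 118 ± 4.42 to 189.9 ± 7.54 CPM with IL-4 in WT and from 159 ± 7.61 to 169.9 ± 6.94 CPM in KO. Over all genes the median interaction log2 fold change was 0.04. Between KO and WT the median of the OXPHOS list was 0.26 in mock and -0.16 with IL-4. The larger part of the difference thus lay in unstimulated cells, where KO against WT fold changes correlated with transcript length (rho = -0.49). Lists of the mitochondrial ribosome (median -0.28, adjusted p = 2.1e-15; adjusted p = 0.59 with an estimated correlation), the TCA cycle (-0.19, adjusted p = 6.7e-07; adjusted p = 0.27 with an estimated correlation) and NRF2-dependent genes (-0.19, adjusted p = 6.7e-06; adjusted p = 0.56 with an estimated correlation) also had medians below 0. In WT the ribosome and NRF2 lists were not called for IL-4 (camera adjusted p = 0.084 and 0.58). In KO their IL-4 medians were -0.17 and -0.22, so for these lists the values do not show a weaker rise. The TCA cycle list shares Sdha, Sdhb, Sdhc and Sdhd with the OXPHOS list. Genes of mitochondrial DNA had a median of 0.42 (adjusted p = 0.0014; adjusted p = 0.61 with an estimated correlation), and those of G2 phase and mitosis 0.54 (adjusted p = 0.00021; adjusted p = 0.80 with an estimated correlation). The mitosis list was not called without both KO 2 libraries (median 0.24, and 0.64 for mitochondrial DNA), nor the mitochondrial DNA list without WT IL-4 library 3 (adjusted p = 0.059; 1.2e-07 to 0.059 over the alternative settings). Single genes that passed over all genes numbered 1 in each of the mitochondrial ribosome, TCA cycle and NRF2 lists and 0 in the mitochondrial DNA and mitosis lists, against 7, 4, 5, 2 and 0 when adjusted over the list alone. With the replicate block the numbers were 23, 6, 8, 5 and 5, and without both KO 2 libraries 0 in each. The interaction fold changes also correlated with transcript length across genes (rho = 0.56), and with the length and GC correction and the replicate block the OXPHOS median was -0.29 (adjusted p = 5.8e-31; 3.4e-50 to 1.1e-24 over the alternative settings) and that of the mitochondrial ribosome -0.16.

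**Figure D4:**
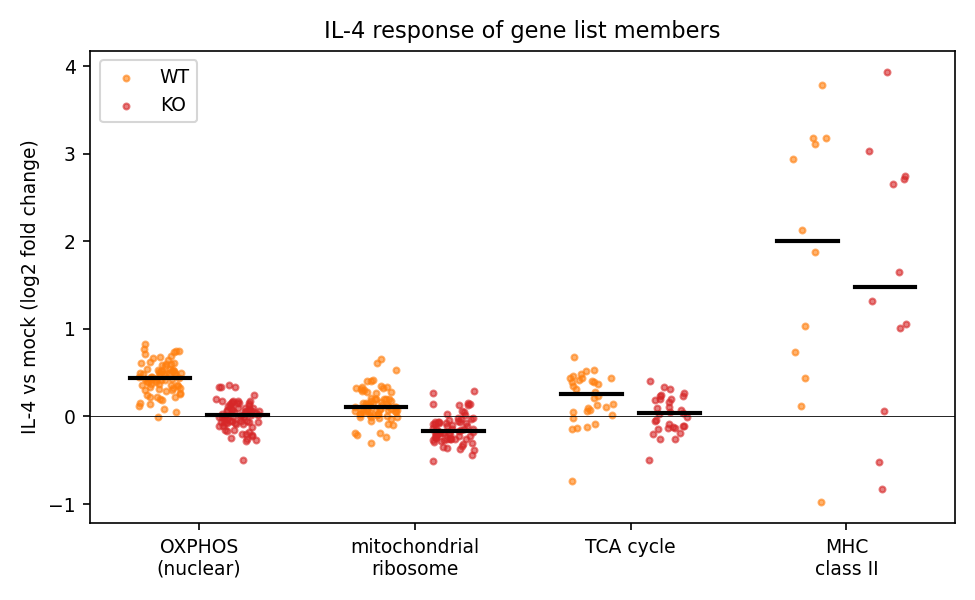
Log2 fold change of IL-4 against mock (y axis) of each measured gene of 4 lists in WT and in KO, with a bar at the median. Nuclear OXPHOS genes have a median of 0.44 in WT and 0.01 in KO.

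Among single genes, the fibronectin gene Fn1 rose more with IL-4 in KO than in WT (1.61, SE 0.33, adjusted p = 0.042), Thbs1 fell less (1.48, SE 0.31, adjusted p = 0.046), as did Vegfa (1.02, SE 0.20, adjusted p = 0.036), and Bex1 rose more (1.36, SE 0.21, adjusted p = 0.015). The heparan sulfate proteoglycan gene Gpc1 (-1.18, SE 0.18, adjusted p = 0.015), the stress gene Ier3 (-1.10, SE 0.17, adjusted p = 0.015), the cyclooxygenase gene Ptgs1 (-0.94, SE 0.16, adjusted p = 0.023), the adenylate kinase gene Ak1 (-1.32, SE 0.21, adjusted p = 0.015) and the class II chaperone gene H2-DMb1 (-0.82, SE 0.15, adjusted p = 0.035) rose less in KO. The interaction did not pass the test for Arg1 (-1.19, SE 0.36, adjusted p = 0.11), Chil3 (-1.13, SE 0.34, adjusted p = 0.12), Mrc1 (-0.13, SE 0.23, adjusted p = 0.80) or Retnla (-0.02, SE 0.39, adjusted p = 0.99). With the replicate block Arg1 (adjusted p = 0.048; 0.010 to 0.25 over the alternative settings) and Chil3 (adjusted p = 0.0078; 0.0078 to 0.41) passed. In total 101 genes passed, 45 with a larger and 56 with a smaller log2 fold change in KO, of which 10 and 6 differed at least 2-fold. Scaled by library size alone, 41 and 24 passed. With the replicate number as a block 1596 passed, 891 with a larger and 705 with a smaller fold change. Without both KO 2 libraries edgeR called 0, with 2292 at an unadjusted p under 0.05, so none of the genes named for the interaction passed there. Leaving out 1 library gave 0 genes without KO IL-4 library 1 (2321 at an unadjusted p under 0.05), 102 and 96 without WT mock library 2 and WT IL-4 library 3, and 14 to 51 without each of the others. DESeq2 and limma-voom, on all 12 libraries, gave 751 and 107.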

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

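Of the tests in this part, the splits of the libraries, the OXPHOS tests with the length and GC correction and with single libraries left out, the neutrophil correlations within a genotype and without both KO 2 libraries, the test of a lower macrophage share and that of Cre copies were chosen only after the results were seen.

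The test of the difference between genotypes singled out 12 genes by their interaction log2 fold change. A larger value in KO was seen for Sun2 (1.65, SE 0.33, adjusted p = 0.041), Fn1 (1.61), Thbs1 (1.48), Bex1 (1.36), Fzd1 (1.16, SE 0.22, adjusted p = 0.036), and Vegfa (1.02). A smaller value was seen for Ak1 (-1.32), Gpc1 (-1.18), Ier3 (-1.10), Ptgs1 (-0.94), Chchd10 (-0.83, SE 0.15, adjusted p = 0.033) and H2-DMb1 (-0.82). With IL-4, Sun2 changed by 1.56 in KO against -0.09 (adjusted p = 0.83) in WT, and Fzd1 by 0.85 against -0.30 (adjusted p = 0.18). The adjusted p of each of the 12 was 0.05 or more in at least 1 alternative setting, with its highest value between 0.087 (Ak1 and Gpc1) and 0.15 (Thbs1).

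By the same test, list medians were 0.54 for G2 phase and mitosis, -0.10 for glycolysis, -0.16 for immediate-early and stress genes, -0.22 for MHC class II, -0.28 for the mitochondrial ribosome, 0.42 for mitochondrial DNA, -0.19 for NRF2-dependent genes, -0.42 for nuclear OXPHOS genes and -0.19 for the TCA cycle. None of these 9 lists passed with an estimated correlation (camera adjusted p = 0.27 to 0.80). Scaled by library size alone, the medians of glycolysis and of immediate-early genes were -0.03 and -0.10. With the length and GC correction and the replicate block they were -0.05 for immediate-early genes, -0.07 for MHC class II and -0.16 for the mitochondrial ribosome. Without both KO 2 libraries they were 0.24 for G2 phase and mitosis, -0.16 for glycolysis and 0.64 for mitochondrial DNA.

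Of 100 splits of the genotype labels within each treatment, the real one included, 5 gave at least the 101 genes of the interaction. The first 50 of these splits were drawn before the number was raised to 100, and among them the real one alone did so (1 of 50), so the share changed sides of 0.05 with the number drawn. The 4 others called 3083, 2637, 1255 and 200 genes. All 4 kept the mock labels and labelled 2 of the 3 WT IL-4 libraries KO, and 2 further splits of that kind called 2 and 0 genes. The structure of the samples that enters such counts includes the genotypes themselves, since by construction part of the difference between KO and WT goes into the contrast when only IL-4 labels are exchanged. Such splits are not draws without an effect, and they separate mock from IL-4 libraries of the same number, so the share does not say whether chance can be excluded. With the replicate block the real split gave 1596 genes and the highest of the others 1, in 1 of 10 splits, too few for a share under 0.05. The contrasts of 2 groups also have only 10 splits each, too few for a share under 0.05. The real split alone gave its count (1 of 10 in each): 4731 genes for KO against WT in mock against 1 in the highest other, and 2579 with IL-4, 3658 for IL-4 in WT and 4152 for IL-4 in KO against 0 each.

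The smaller IL-4 response of nuclear OXPHOS genes in KO was set against 3 technical explanations. Among 10000 random lists matched on length, GC content and expression, drawn from the 50 nearest genes of each member, the middle 95% of medians lay between -0.22 and -0.13 and the lowest at -0.25, against -0.42 for the list. The random medians centred on -0.17. Their genes were drawn singly, so their spread does not allow for correlation between OXPHOS genes. With the length and GC correction and the replicate block the median of the OXPHOS list was -0.29, so part of its size went with those trends as fitted. The rest was not removed by this correction, which would leave any trend that its splines did not capture. Without any 1 library and without the correction the median of the list lay between -0.55 (WT mock library 2) and -0.34 (WT IL-4 library 2). What stays open is whether LKB1 loss, not separable here from the Cre insertion, may account for the difference. That hypothesis was found and tested on the same data, and the list's call is lost when the correlation is estimated.

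The higher neutrophil genes in KO may come from more neutrophil RNA in the KO cultures, which began as bone marrow, with no sort named in the labels. For S100a8, S100a9, Ltf, Camp, Ngp, Retnlg and Lcn2, the last also in the classical inflammatory list, 14 of 14 fold changes were above 0, and the abundant Ltf and Ngp went from 64.4 ± 29.0 and 60.8 ± 24.2 CPM in WT mock to 219 ± 98.5 and 183 ± 67.6 in KO mock. These rises restate the pattern and do not bear on its cause. Over the 12 libraries, which mix the genotypes, the lowest of 21 pairwise correlations was r = 0.942 and rho = 0.942 (highest adjusted permutation p = 2e-05 for each), with r at least 0.903 without the 2 farthest libraries and 0.901 without both KO 2 libraries. Within the 6 libraries of a genotype, where mock and IL-4 libraries of the same number may share a culture, the lowest values were r = 0.826 and rho = 0.771 in WT (highest adjusted exact permutation p = 0.043 and 0.10) and r = 0.838 and rho = 0.886 in KO (0.036 and 0.033). The correlations show that these genes moved together, not the source of their RNA. A lower macrophage share would raise the markers of all other cell types alike, and the medians in mock were 1.47 for neutrophils and 2.46 for the erythroid list against 0.05 for dendritic cells (0 of 11 rose), -0.17 for lymphocytes (0 of 8 rose) and -0.34 for eosinophils (1 of 4 rose and 1 fell; camera adjusted p = 0.75), with 0.68 for stromal (3 of 14 rose), 0.50 for mast cell and basophil (0 of 8) and 0.18 for monocyte markers (4 of 11 rose and 4 fell) above 0, so it stays open, since several dendritic and lymphocyte markers lie near the detection floor or are also made by macrophages.

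Lyz2 near 0 in both KO 2 libraries was weighed against reads lost to its paralog, fewer macrophages and the Cre insertion. The summed CPM of Lyz1 and Lyz2 in KO 2 was at most 0.780% of the mean sum in KO 1 and 3, and 17 macrophage markers had a median ratio of KO 2 over KO 1 and 3 of 0.935 in mock and 0.9498 with IL-4, which argue against the first and second. Lyz2 stood at 0.102% and 0.147% of the WT mean in KO 2 and at 49.9% to 53.5% in KO 1 and 3. A candidate explanation is that the donor of the KO 2 cultures carried 2 copies of the Cre insertion, which replaces Lyz2 sequence, and those of KO 1 and 3 carried 1. The genotype of each donor was not analysed here.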

How the results depend on the processing

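The length and GC correction and the fits without both KO 2 libraries were added after seeing the data. Counts of genes stayed within 1.5 times of the reported ones except as follows, and the cause was not tested unless fewer samples or a stricter threshold are the alternative. With an absolute log2 fold change of at least 1 the counts were 841 and 547 for KO against WT in mock and with IL-4, 901 and 968 for IL-4 in WT and KO, and 16 for the interaction. Without both KO 2 libraries KO against WT with IL-4 gave 1596. Leaving out 1 library gave 3293 to 5212, 1658 to 2686, 2951 to 3719, 3062 to 4641 and 0 to 102 genes in the same order, with 1658 without WT IL-4 library 1. The interaction gave 65 with library size alone, 1596 with the replicate block, 1343 with the block and the length and GC correction, 751 with DESeq2, 0 without both KO 2 libraries (edgeR, 2292 at an unadjusted p under 0.05) and 23 with that and the correction. Without WT mock libraries 1, 2 and 3 it gave 14, 102 and 23, without KO mock libraries 18, 51 and 38, without WT IL-4 libraries 36, 51 and 96, and without KO IL-4 libraries 0 (2321 at an unadjusted p under 0.05), 26 and 21. Lists called by camera numbered 15, 15, 12, 10 and 9 in that order, and 0, 2, 2, 1 and 0 with an estimated correlation. CREB targets and erythroid markers held for KO against WT with IL-4, the IL-4 and MHC class II lists for IL-4 in WT, and the IL-4 list for IL-4 in KO. With the block and correction the interaction had 14 lists, and without 1 library lists ran from 14 to 19, 11 to 17, 12 to 15, 8 to 13 and 8 to 11. The correlation of IL-4 responses was 0.828 over all genes and 0.895 over genes called in WT, KO or both. Over the genes so called in each fit without 1 library it was 0.878 to 0.902. Over the genes reported in every contrast, the largest changes and the called members of called lists, the values that changed sign were not called under the reported settings: Mrc1 in KO against WT with IL-4 (-0.021 to 0.27 without 1 library), Stk11 in WT with IL-4 (-0.077 to 0.19), Lyz2 in KO with IL-4 (-1.03 to 0.13) and the interactions of Lyz2 (-0.52 to 0.62) and Retnla (-0.52 to 0.36). The Retnla interaction was 0.037 with library size alone, 0.0052 with the replicate block, 0.16 with the correction, 0.17 with both, 0.34 without both KO 2 libraries, 0.53 with that and the correction, 0.080 with limma-voom and 0.048 with DESeq2. Other list members were not followed through all settings, and some changed sign with the correction, among them Slc38a1, singled out after its values were seen and called in KO against WT in mock (-0.42, edgeR adjusted p = 0.00051, and 0.05 with the correction, 0.69). Over the genes followed and all settings 6451 values kept their direction and side of the threshold, 237 lost a call, 23 gained one and 22 changed sign. Most losses and sign changes lay in the interaction, where 429 values kept both, 191 lost a call, 5 gained one and 19 changed sign. WT and KO libraries share only a number: those of the same number correlated at -0.126, -0.319 and -0.091 in mock and -0.273, -0.209 and 0.175 with IL-4. A block on it gave 4604 and 2496 genes for KO against WT, with MHC class II and mitochondrial DNA in mock and growth factors and matrix with IL-4 newly called, and fatty acid oxidation and Klf1 in mock and chemokine receptors and Klf1 with IL-4 not called. For the contrasts with paired libraries the replicate block gave 4592 and 5284 genes for IL-4 in WT and KO. It called the LXR, mitochondrial DNA, monocyte and neutrophil lists for IL-4 in KO, the chemokine receptor, monocyte, growth factor and complement lists for the interaction, Lyz2 in both IL-4 contrasts and Stk11 in KO. Apart from these and the interaction genes already given, it changed no other call of a list or of a gene value reported. With only genes of a CPM of at least 1 in 3 libraries, the fatty acid synthesis and oxidation and classical inflammatory lists in mock and the chemokine receptor, monocyte and osteoclast lists with IL-4 were not called for KO against WT. Settings planned for normalized values were not run, since counts were used. None of 61 called lists changed the sign of its median between scalings. Without the replicate block the simulated interaction test found 28% of genes changed 1.5-fold, so smaller differences were mostly not detectable by that fit. The simulated libraries were drawn independently, so they do not say what the fit with the block could detect.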

Other observations

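Of the tests in this part, those with the length and GC correction and those without both KO 2 libraries were chosen only after the results were seen.

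Beyond the groups described, IL-4 also changed immediate-early and chemokine receptor genes in WT cells, eosinophil markers in both genotypes, and osteoclast, interferon-stimulated and cholesterol synthesis genes in KO cells. Of 20 immediate-early and stress genes 10 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.21 with an estimated correlation), with Ier3 at 3.35 (SE 0.13), Klf4 at 2.53 (SE 0.19) and Fos at -0.78 (SE 0.08). Of 15 chemokine receptor genes 5 rose and 6 fell, the same when adjusted over the list alone (adjusted p = 0.0035; adjusted p = 0.21 with an estimated correlation). The complement receptor gene C5ar1 changed by -1.46 (SE 0.08) and Cxcr4 by -1.19 (SE 0.09). Of 4 eosinophil markers Ear2 (3.79, SE 0.17) and Siglecf (0.86, SE 0.11) rose, also when adjusted over the list alone (adjusted p of the list = 0.00078; adjusted p = 0.074 with an estimated correlation). In KO cells the same markers rose, Ear2 by 2.85 (SE 0.15) and Siglecf by 1.33 (SE 0.12; adjusted p of the list = 0.0016; adjusted p = 0.17 with an estimated correlation). Of 15 genes of osteoclast formation and fusion 7 rose and 1 fell in KO (8 and 1 adjusted over the list alone; adjusted p = 3.2e-05; adjusted p = 0.55 with an estimated correlation), with Ocstamp at 6.86 (SE 0.34) and the integrin gene Itgb3 at 3.02 (SE 0.29). Of 37 interferon-stimulated genes 14 rose and 2 fell in KO (15 and 2 adjusted over the list alone; adjusted p = 0.0026; adjusted p = 0.76 with an estimated correlation). Of 24 cholesterol synthesis genes 11 rose and none fell (12 adjusted over the list alone, 4 without both KO 2 libraries; adjusted p = 0.011; adjusted p = 0.80 with an estimated correlation), and that list was not called without both KO 2 libraries or without KO mock library 1 (adjusted p = 0.068 and 0.061; 0.00032 to 0.068 over the alternative settings).

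Under IL-4, KO cells also differed from WT in genes of other myeloid functions. Of 15 chemokine receptor genes 5 were higher and 3 lower (6 and 3 adjusted over the list alone; adjusted p = 0.030; adjusted p = 0.30 with an estimated correlation), with C5ar1 at 0.92 (SE 0.08), Ccr1 at 0.86 (SE 0.11) and Cxcr4 at 0.85 (SE 0.09). Of 11 monocyte markers Ly6c2 (1.86, SE 0.34) was among 3 that were higher, and Itgal (-0.47, SE 0.07) among 2 that were lower, the same counts as adjusted over the list alone (adjusted p = 0.040; adjusted p = 0.50 with an estimated correlation). Of 15 genes of osteoclast formation 5 were higher and 3 lower, the same as adjusted over the list alone (adjusted p = 0.041; adjusted p = 0.58 with an estimated correlation), with Acp5 at 1.01 (SE 0.07) and Mmp14 at 0.65 (SE 0.06). These 3 lists were not called with the length and GC correction, and the osteoclast list was not called without both KO 2 libraries. Each also lost its call without WT IL-4 library 2, the chemokine receptors without KO IL-4 library 3, the monocyte markers without WT mock library 3 or WT IL-4 library 3, and the osteoclast list without WT mock library 1 or 3, KO mock library 3 or KO IL-4 library 2 or 3. Over the alternative settings their adjusted p lay between 0.022 and 0.14, 0.0035 and 0.10, and 0.0036 and 0.19. In the interaction, the immediate-early list (adjusted p = 0.00059; adjusted p = 0.27 with an estimated correlation) had 2 genes with a smaller response in KO, Jun (-0.63, SE 0.10) and Ier3 (-1.10, SE 0.17), against 3 adjusted over the list alone. The glycolysis list (adjusted p = 0.00075; adjusted p = 0.56 with an estimated correlation) had 2, Eno1 (-0.51, SE 0.09) and Pgk1 (-0.47, SE 0.09), against 7 adjusted over the list alone and with the replicate block. The MHC class II list (adjusted p = 0.033; adjusted p = 0.61 with an estimated correlation) had 1, against 2 adjusted over the list alone and 4 with the block, and was not called with the length and GC correction and the block (adjusted p = 0.13; 0.0020 to 0.37 over the alternative settings). It was called without WT IL-4 library 3, KO mock library 3, KO IL-4 library 2 or WT mock library 1, and not without any 1 of the other 8 libraries.

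Stk11 and Lyz2 both lie on chromosome 10, so sequence from another strain carried along with the targeted loci might change genes near them. Of 303 genes within 10 Mb of either 45 (14.9%) were called for KO against WT in both mock and IL-4, against 1671 of 13062 (12.8%) on other chromosomes, an odds ratio of 1.19 (95% interval 0.843 to 1.65, two-sided Fisher's exact p = 0.30). The interval holds both no enrichment and a moderate one, so the question stays open.

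The authors' deposited table called 2158 genes higher and 2751 lower for KO against WT in mock, 1285 and 1566 with IL-4, 1955 and 1889 for IL-4 in WT and 2331 and 1982 in KO. Of those, 4642, 2544, 3619 and 4079 were also called here.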
